A study of Aspergillus nidulans with 12 samples.

How the data were processed

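The series holds 12 arrays with 2 colours each of Aspergillus nidulans RNA. Per the labels, Cy5 carried ∆msbA or ∆MHD and Cy3 carried TNO2A3 of the same medium, with 3 biological replicates in each of 4 groups. The labelling protocol text also speaks of treatments that match no strain here, and the strain labels were followed. The authors scanned a custom array with a GenePix scanner and read spots with Agilent Feature Extraction 9.5.3.1. The deposited files for each array give mean spot and median local background signals as intensity, with processed signals and spot flags. Each array held 43803 gene spots for 11143 genes, at 1 probe per gene, with 3 to 14 spots per gene and a median of 4. A deposited table of signed values for the whole series was left out because its 12 columns carry no sample names. The tool that made it is not given in the sources used here.

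Spots with uneven pixels or deviating from their repeats were dropped, between 1200 and 1510 per array, and saturated spots were kept, at most 48 per channel. Mean signals were corrected for background by normexp with an offset of 50 and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with statmod 1.5.0. Log2 ratios of Cy5 over Cy3 were averaged over the spots of a gene. A gene was tested where its probe was well above background in either colour on all 3 arrays of at least 1 group, which 8538 genes met. Of these 6 lacked a value on an array, so 8532 were tested and 2605 lay below the filter. Gene symbols came from the RefSeq table, which held 8125 of the tested IDs, 739 with a symbol. That AN7041 is msbA, and the roles given for genes, are background knowledge. Input tables were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

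The means of all 4 groups were fitted in limma to all 12 arrays, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Each mutant was compared with TNO2A3 in each medium, its effect between media, and the mutants with each other in each medium. No dye swap was made, so a dye effect of a probe is mixed with the strain in the 4 comparisons against TNO2A3 and cancels in the 4 differences. For TNO2A3 between media, Cy3 intensities were brought to one average distribution (Aquantile). The 2 arrays of one medium and number were averaged to 1 value, which gave 3 against 3. The design text counts 3 repetitions of each point, so both mutants of a medium and number were taken to share a TNO2A3 sample. Where one strain or medium was not well above background on any array, the fold is given as a lower bound. For a gene dim in both colours in YUU no difference between media is given, though such genes were tested and counted.

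Gene lists, 30 with 295 IDs in all, were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives. AN5781 and AN1551 were dropped from their lists, since the annotation gave them another function, and 258 listed IDs were measured. The 29 lists with at least 3 measured members were tested by camera with a correlation of 0.01, and beside it with an estimated correlation and by fry. Of 261 tests camera called 65, none of which passed with the estimated correlation. The rule for named genes gave AN7041 first, then up to 6 genes with the largest change in each direction among those past the threshold on the same side on all arrays, or with groups that did not overlap. It also gave up to 4 called members of each list with the largest change, and other members only in lists of 3 or fewer. From these the text names a part, and genes whose call was kept under the alternatives were taken first, so the named genes are steadier than those the rule gave.

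The number of arrays limits the precision. On tested simulated data with 50 changed genes per size, the fit called 80 to 84% of 1.25-fold changes and 98 to 100% of 2-fold changes against TNO2A3, with 5.56 to 7.32% of calls false. For the effect between media it called 50 to 64% and 96%, with 7.53 to 8.89% of calls false. The fit takes a gene to vary alike in all groups. These rates may thus not hold for ∆msbA on Avicel, whose array 1 lay apart. A simulated log2 change of 2 was read as 1.94 in bright spots and 1.65 in dim ones, so changes of dim genes are read too small. Pairing of replicate numbers was checked by correlating deviations from group means (closing section).

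The alternatives set beforehand were no background correction, the processed signals of Feature Extraction without loess, no filter, a stricter filter of both colours on all arrays (6093 genes), slide or replicate number as a fixed block, a random block of medium and number, log ratios scaled to one median absolute deviation, only the groups compared, and leaving out each replicate number. For TNO2A3 median scaling, quantile normalization and a separate-channel fit were also run. After the data were seen a replicate block within each medium and a fit without array 1 of ∆msbA on Avicel were added.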

Results

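Transcript levels of Aspergillus nidulans were read for 11143 genes on 12 arrays with 2 colours each. On every array a mutant, ∆msbA or ∆MHD, was labelled with Cy5 and the strain TNO2A3, grown in the same medium, with Cy3. Cultures were kept in complete medium (YUU) for 24 h, or moved after washing to minimal medium with Avicel, a crystalline cellulose and the sole carbon source, for 24 h. Effects of and responses to Avicel below thus include washing, transfer and minimal medium, which these arrays cannot separate from the carbon source. Each of the 4 groups, of a mutant and a medium, had 3 biological replicates per the labels. The median Cy3 signal of an array lay between 73.6 and 111 units and the median Cy5 signal between 105 and 220, over backgrounds of 38 to 41. Between 61.2 and 71.5% of spots were well above background in Cy3, and 64.5 to 76.3% in Cy5. After filtering, 8532 genes were tested in each of 9 comparisons, and 30 gene lists with 258 measured members were followed. A log2 value is the mutant over TNO2A3 unless another pair is named, and SE is its standard error from the limma fit with 3 arrays per group. List counts are of measured members, and the adjusted p of a list is from camera. In comparisons against TNO2A3 and between mutants slide as a block left the log2 values and list medians as they were, so only values within each slide are given there. What most genes without a stated role encode is not given in the sources used here.

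The first question was whether the deleted gene itself was low. AN7041 (msbA), which encodes a signalling mucin homologous to yeast Msb2, fell in ∆msbA on each array. In YUU its log2 ratios were -2.40, -2.51 and -2.60 (mean -2.50, 5.67-fold, SD 0.10, n = 3, adjusted p = 4.94e-10), and on Avicel -2.33, -2.29 and -2.40 (mean -2.34, 5.07-fold, SD 0.06, n = 3, adjusted p = 9.68e-11). In ∆MHD the same gene fell in YUU, at -0.30, -0.66 and -0.67 (mean -0.55, 1.46-fold, SD 0.21, n = 3, adjusted p = 0.000537). On Avicel ∆MHD arrays read 0.31, 0.12 and 0.14 (mean 0.19, 1.14-fold, SD 0.11, n = 3, adjusted p = 0.0359), a call that was lost with the processed signals (0.24), with ratios scaled to one spread (0.16), and without replicate 1 (0.13), replicate 2 (0.23) or replicate 3 (0.21). Within slides 2 and 3 the YUU values were -2.60 and -2.46 in ∆msbA, and -0.67 and -0.48 in ∆MHD. Within slides 1 and 2 the Avicel values were -2.31 and -2.40 in ∆msbA, and 0.21 and 0.14 in ∆MHD. The position of the probe is not given, and a probe outside the deleted part would not check the deletion. Which gene MHD stands for is not given in the sources used here, so it could not be followed.

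**Figure D1:**
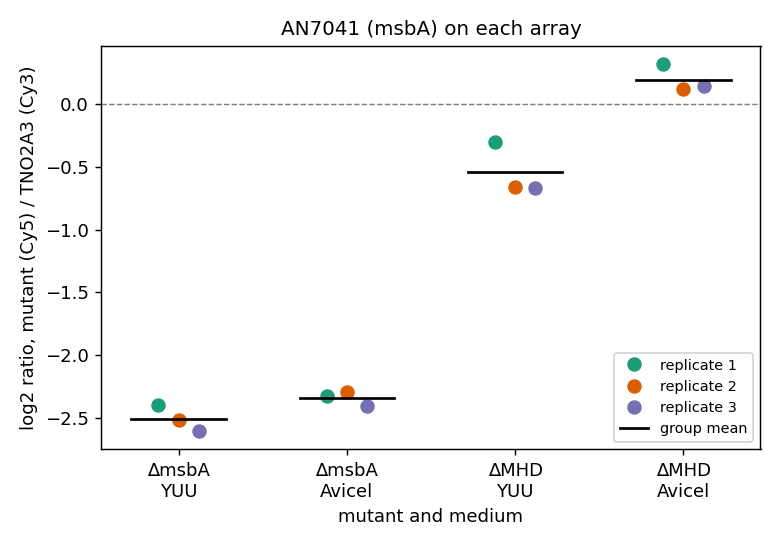
Log2 ratio (mutant over TNO2A3) of AN7041 on each of 12 arrays in 4 groups, with colours for replicate numbers and a bar at the group mean. The means were -2.50 and -2.34 in ∆msbA, and -0.55 and 0.19 in ∆MHD, for YUU and Avicel.

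Which transcripts depended on msbA in complete medium? Apart from AN7041, the largest losses in ∆msbA were in AN2571 (log2 -2.46, SE 0.20, 5.49-fold, adjusted p = 2.06e-06) and AN7792 (log2 -1.86, SE 0.06, 3.63-fold, adjusted p = 3.44e-09), and the largest gains in AN8333 (log2 2.69, SE 0.14, 6.46-fold, adjusted p = 6.51e-08) and AN7217 (log2 2.06, SE 0.10, 4.18-fold, adjusted p = 5.2e-08). All 3 penicillin cluster genes rose, namely AN2622 (isopenicillin N synthase, log2 1.69), AN2623 (acyltransferase, log2 1.5) and AN2621 (ACV synthetase, log2 1.22). Their median was 1.5, 1.39 within slide 2 and 1.55 within slide 3 (adjusted p = 0.00545, 0.751 with estimated correlation). Of 6 heat shock proteins 4 fell and none rose, and 2 did not pass. AN0858 (log2 -1.22), hsp70 (AN5129, log2 -0.60) and hsp90 (AN8269, log2 -0.54) were among those called. The median was -0.36, -0.29 within slide 2 and -0.39 within slide 3 (adjusted p = 0.0162, 1 with estimated correlation). In total 3158 of 8532 genes passed, 1732 higher and 1426 lower, and 83 of them by more than 2-fold (50 and 33). Above 2-fold there were 315 with the processed signals. 5798 of all 8532 genes had all 3 arrays on one side (25% by chance). 3511 genes passed with slide as a block.

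Counts of higher and lower members in lists without a called shift were 2 and 0 of 23 in cellulose breakdown (AN7891, lytic polysaccharide monooxygenase AA9, log2 1.53), 5 and 3 of 21 in MAP kinase signalling (sskA, AN7697, response regulator, log2 -0.70) and 6 and 3 of 14 in cell wall synthesis (AN8444, mixed-linkage glucan synthase, log2 -0.66). They were 0 and 2 of 11 in starvation and autolysis (AN5131, autophagy protein Atg8, log2 -0.47), 3 and 0 of 14 in asexual development (flbB, AN7542, upstream activator of conidiation, log2 0.20) and 2 and 0 of 4 in the emericellamide cluster (AN2549, acyl-CoA ligase, log2 0.42). Further counts were 1 and 4 of 8 in oxidative stress (cat1, AN9339, catalase, log2 -0.57), 0 and 4 of 7 in osmolytes and trehalose (AN5523, trehalose-6-phosphate synthase, log2 -0.42) and 1 and 3 of 8 in gluconeogenesis, glyoxylate and acetate (AN5634, isocitrate lyase, log2 -0.89). Higher and lower members numbered 2 and 0 of 7 in sexual development, 1 and 2 of 10 in glycolysis, 1 and 0 of 4 in ethanol metabolism, 4 and 1 of 11 in nitrogen metabolism, 2 and 1 of 7 in iron and siderophores, 1 and 0 of 3 in strain markers and 0 and 1 of 21 in the sterigmatocystin cluster. No member passed in hemicellulose breakdown, starch breakdown, carbon regulators, sugar transport, hydrophobins, orsellinic acid, asperthecin, terrequinone, dba polyketide, austinol, asperfuranone and monodictyphenone. Members dim in both colours, without a fold, were 4 of 6 in starch breakdown, 3 of 6 in hydrophobins, 3 of 3 in terrequinone, 2 of 4 in ethanol metabolism, 16 of 21 in sterigmatocystin, 9 of 10 in dba polyketide, 5 of 6 in austinol, 4 of 5 in asperfuranone and 2 of 3 in monodictyphenone. The other lists had fewer dim than not, such as 10 of 23 in cellulose and 6 of 16 in hemicellulose breakdown. MAP kinase signalling 10 and 3, starvation and autolysis 0 and 1, glycolysis 1 and 1, iron and siderophores 3 and 1 and sterigmatocystin 0 and 0 were higher and lower adjusted over the list alone, with other counts unchanged. Starvation and autolysis, asexual development, glycolysis, dba polyketide and austinol differed in sign between median, mean and test. Without replicate 2 the count of called genes was 1926, and 2075 without replicate 3. The share of called genes that were higher was 54.8%, against 45% with the processed signals, which read AN8333 at 2.82 and AN2571 at -2.56.

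What did ∆MHD change in the same medium? The largest gains were in AN2622 (log2 1.38, SE 0.12, 2.6-fold, adjusted p = 7.18e-05) and gatA (AN2248, log2 1.22, SE 0.08, 2.33-fold, adjusted p = 1.24e-05), and the largest losses in AN6940 (log2 -0.79, SE 0.07, 1.73-fold, adjusted p = 8.96e-05) and AN2794 (log2 -0.75, SE 0.06, 1.68-fold, adjusted p = 5e-05). All 3 penicillin cluster genes rose. AN2623 (log2 0.94) and AN2621 (log2 0.89) were among them. Their median was 0.94, 0.97 within slide 2 and 0.98 within slide 3 (adjusted p = 0.00036, 0.776 with estimated correlation). Of 10 glycolysis genes 5 rose and none fell, and 5 did not pass. AN8689 (glucokinase, log2 0.34, without replicate 2 0.34, not called, without replicate 3 0.33, not called) was among those called. Their median was 0.16, 0.18 within slide 2 and 0.15 within slide 3 (adjusted p = 0.0352, 0.776 with estimated correlation). The glycolysis call was lost with the processed signals (camera adjusted p = 0.348). In total 1515 of 8532 genes passed, 886 higher and 629 lower, and 2 of them by more than 2-fold (2 and 0). Above 2-fold there were 33 with the processed signals, 15 with ratios scaled to one spread and 4 without background correction. 4267 of all 8532 genes had all 3 arrays on one side (25% by chance). 1942 genes passed with slide as a block.

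Counts of higher and lower members in the other lists were 2 and 2 of 8 in gluconeogenesis, glyoxylate and acetate (fbp1, AN5604, fructose-1,6-bisphosphatase, log2 -0.36), 3 and 1 of 11 in nitrogen metabolism (AN9470, urate oxidase, log2 0.65) and 2 and 0 of 7 in iron and siderophores (AN5823, ornithine monooxygenase, log2 0.50). Higher and lower members numbered 1 and 0 of 23 in cellulose breakdown, 4 and 1 of 21 in MAP kinase signalling, 2 and 2 of 14 in cell wall synthesis, 2 and 0 of 11 in starvation and autolysis, 2 and 0 of 8 in oxidative stress, 1 and 1 of 7 in osmolytes and trehalose and 1 and 0 of 6 in heat shock proteins. No member passed in hemicellulose breakdown, starch breakdown, carbon regulators, sugar transport, hydrophobins, asexual development, sexual development, orsellinic acid, asperthecin, terrequinone, emericellamide, ethanol metabolism, strain markers, sterigmatocystin, dba polyketide, austinol, asperfuranone and monodictyphenone. Members dim in both colours, without a fold, were 4 of 6 in starch breakdown, 4 of 7 in sugar transport, 4 of 6 in hydrophobins, 3 of 3 in terrequinone, 2 of 4 in ethanol metabolism, 17 of 21 in sterigmatocystin, 9 of 10 in dba polyketide, 5 of 6 in austinol, 4 of 5 in asperfuranone and 2 of 3 in monodictyphenone. Fewer were dim than not elsewhere, such as 11 of 23 in cellulose and 7 of 16 in hemicellulose breakdown. Cellulose breakdown 0 and 0, MAP kinase signalling 7 and 1, osmolytes and trehalose 1 and 4, gluconeogenesis, glyoxylate and acetate 2 and 3 and nitrogen metabolism 4 and 1 were higher and lower adjusted over the list alone, with other counts unchanged. Cellulose breakdown, sugar transport, hydrophobins, dba polyketide and austinol differed in sign between median, mean and test. The share of called genes that were higher was 58.5%, against 43.8% with the processed signals. Without replicate 1, 2 or 3 the count was 678, 516 and 521, and with ratios scaled to one spread it was 2779.

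**Figure D2:**
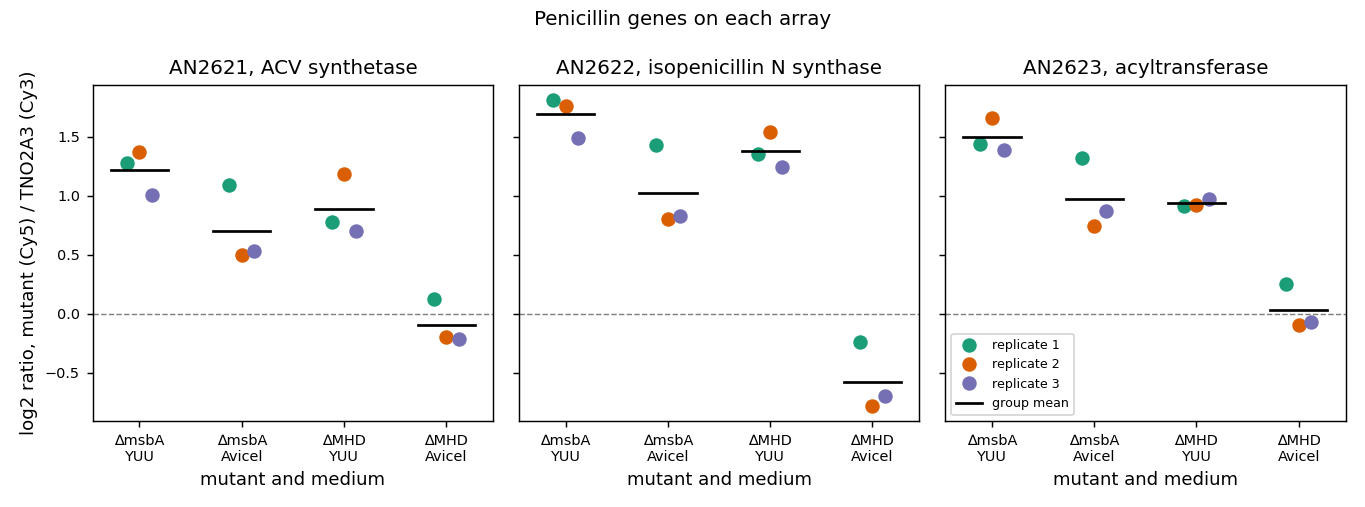
Log2 ratio (mutant over TNO2A3) of AN2621, AN2622 and AN2623 on each array, by group, with colours for replicate numbers. AN2622 averaged 1.69 and 1.38 in YUU, and 1.02 and -0.57 on Avicel, in ∆msbA and ∆MHD.

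Which transcripts depended on msbA when cellulose was the carbon source? The largest gains in ∆msbA on Avicel were in ccpA (AN10109, log2 4.21, SE 0.05, 18.4-fold, adjusted p = 3.01e-14) and ivoA (AN10576, conidiophore pigment, log2 4.12, SE 0.08, 17.4-fold, adjusted p = 2.75e-12), and the largest losses in AN8619 (log2 -4.88, SE 0.12, 29.4-fold, adjusted p = 1.78e-11) and AN3339 (log2 -4.81, SE 0.08, 28.1-fold, adjusted p = 6.3e-13). Of 6 hydrophobins 5 rose and none fell, and 1 did not pass. AN1837 (log2 3.75), rodA (AN8803, log2 3.59) and dewA (AN8006, log2 3.29) were among those called. The median was 3.07, 3.03 within slide 1 and 3.16 within slide 2 (adjusted p = 4.73e-05, 0.219 with estimated correlation). Of 14 asexual development genes 10 rose and 1 fell, and 3 did not pass. yA (AN6635, conidial laccase, log2 1.73) and brlA (AN0973, conidiation regulator, log2 1.49) were among those called. Their median was 0.26, 0.21 within slide 1 and 0.32 within slide 2 (adjusted p = 0.00251, 0.273 with estimated correlation). Of 11 starvation and autolysis genes 9 rose and 1 fell, and 1 did not pass. mep20 (AN7962, metalloprotease, log2 2.30) and AN5558 (alkaline protease, log2 1.75) were among those called. Their median was 0.44, 0.40 within slide 1 and 0.53 within slide 2 (adjusted p = 0.00199, 0.219 with estimated correlation). All 10 dba polyketide cluster genes fell. AN7897 (log2 -2.57) was among them. The median was -2.41, -1.91 within slide 1 and -3.46 within slide 2 (adjusted p = 1.99e-06, 0.527 with estimated correlation).

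Of 16 hemicellulose breakdown genes 11 fell and 2 rose, and 3 did not pass. AN3358 (endo-mannanase GH5, log2 -1.31) was among those called. Their median was -0.60, -0.39 within slide 1 and -0.86 within slide 2 (adjusted p = 0.0381, 0.607 with estimated correlation). All 3 penicillin cluster genes rose, namely AN2622 (log2 1.02), AN2623 (log2 0.98) and AN2621 (log2 0.70). The median was 0.98, 1.03 within slide 1 and 0.83 within slide 2 (adjusted p = 0.0418, 0.539 with estimated correlation). All 5 orsellinic acid cluster genes rose. AN7914 (log2 2.07) was among them. Their median was 1.52, 1.58 within slide 1 and 1.27 within slide 2 (adjusted p = 0.0442, 0.539 with estimated correlation). All 6 austinol cluster genes rose. AN9249 (log2 1.76, TNO2A3 well above background on 1 of 3 arrays) and AN9253 (at least 2.27-fold higher, adjusted p = 2.81e-09) were among them. Their median was 0.42 (0.41 with dim members at their bound), 0.40 within slide 1 and 0.45 within slide 2 (adjusted p = 0.00251, 0.265 with estimated correlation). With slide as a block the hemicellulose (camera adjusted p = 0.053), penicillin (0.0604) and orsellinic acid (0.0787) calls were lost. In total 4240 of 8532 genes passed, 2197 higher and 2043 lower, and 374 of them by more than 2-fold (193 and 181). Above 2-fold there were 844 with the processed signals, 219 with ratios scaled to one spread and 151 under the stricter filter. 5436 of all 8532 genes had all 3 arrays on one side (25% by chance). 4568 genes passed with slide as a block. With only the groups compared in the fit the count was 2473.

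Array 1 of ∆msbA on Avicel lay apart from arrays 2 and 3 in several lists. The cellulose breakdown medians of the 3 arrays were 0.34, -1.19 and -1.48, those of starch breakdown 0.65, -0.96 and -1.35, those of hemicellulose breakdown 0.11, -0.85 and -0.86, those of the dba cluster -1.46, -2.41 and -3.46, those of orsellinic acid -0.018, 2.83 and 1.27, and those of terrequinone -0.18, 2.28 and 0.68. Without that array 3 cellulose genes were higher and 16 lower (median -1.31, camera adjusted p = 1.21e-06), 0 and 6 starch genes (median -1.20, adjusted p = 9.06e-05), and 0 and 7 glycolysis genes (median -0.29, adjusted p = 0.0168), and the oxidative stress list also passed (adjusted p = 0.0446). The higher and lower counts became 1 and 12 in hemicellulose breakdown, 8 and 0 in asexual development, 3 and 1 in MAP kinase signalling (median 0.10 to 0.02), 2 and 0 in heat shock proteins, 3 and 0 in osmolytes and trehalose, 1 and 3 in sugar transport, 4 and 1 in sexual development, 3 and 0 in iron and siderophores, 0 and 1 in emericellamide and in monodictyphenone and 0 and 0 in asperfuranone. The count of called lists was then 12 against 8, the dba median -2.86, the terrequinone median 1.48 (from 0.93) and the orsellinic acid median 2.19, with 3913 genes called. Counts of higher and lower members in the other lists were 5 and 14 of 23 in cellulose breakdown (AN8068, endoglucanase GH5, log2 -1.63), 1 and 4 of 7 in carbon regulators (creA, AN6195, carbon catabolite repressor, log2 -0.38) and 2 and 2 of 7 in sugar transport (AN0250, xylose transporter, log2 -0.70). They were 6 and 0 of 21 in MAP kinase signalling (skn7, AN3688, response regulator, log2 0.46), 5 and 3 of 14 in cell wall synthesis (ags1, AN3307, alpha-1,3-glucan synthase, log2 -0.92) and 4 and 0 of 7 in sexual development (AN7349, Hulle cell alpha-1,3-glucanase, log2 1.88). Further counts were 1 and 0 of 2 in the asperthecin cluster (AN6001, log2 0.30), 0 and 2 of 4 in the emericellamide cluster (AN2545, nonribosomal peptide synthetase, log2 -0.63) and 2 and 6 of 8 in oxidative stress (AN5918, catalase, log2 -0.93). Higher and lower members numbered 0 and 3 of 6 in starch breakdown, 3 and 0 of 3 in the terrequinone cluster, 3 and 1 of 7 in osmolytes and trehalose, 4 and 1 of 6 in heat shock proteins, 0 and 5 of 10 in glycolysis, 4 and 0 of 8 in gluconeogenesis, glyoxylate and acetate, 0 and 3 of 4 in ethanol metabolism, 0 and 4 of 11 in nitrogen metabolism, 4 and 0 of 7 in iron and siderophores, 0 and 1 of 3 in strain markers, 4 and 12 of 21 in the sterigmatocystin cluster, 0 and 1 of 5 in the asperfuranone cluster and 0 and 2 of 3 in the monodictyphenone cluster. Starch breakdown 0 and 4, sexual development 5 and 0, gluconeogenesis, glyoxylate and acetate 5 and 0 and asperfuranone 0 and 0 were higher and lower adjusted over the list alone, with other counts unchanged. Cell wall synthesis differed in sign between median, mean and test. With ratios scaled to one spread AN8619 read -3.87 and AN10109 3.34, and with the processed signals -5.79 and 5.13.

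The same question was asked of ∆MHD on Avicel. The largest losses were in AN11584 (log2 -6.16, SE 0.36, 71.4-fold, adjusted p = 7.15e-08) and AN7903 (log2 -5.27, SE 0.29, 38.6-fold, adjusted p = 3.74e-08), and the largest gains in AN5046 (log2 4.93, SE 0.08, 30.5-fold, adjusted p = 5.5e-13) and ivoA (AN10576, log2 4.83, SE 0.08, 28.4-fold, adjusted p = 1.33e-12). Of 23 cellulose breakdown genes 20 fell and 1 rose, and 2 did not pass. cbhC (AN5282, cellobiohydrolase GH6, log2 -3.80), cbhB (AN0494, cellobiohydrolase GH7, log2 -3.66) and AN5176 (cellobiohydrolase GH7, log2 -3.49) were among those called. Their median was -2.06 (-2.10 with dim members at their bound), -2.14 within slide 1 and -1.90 within slide 2 (adjusted p = 3.65e-07, 0.394 with estimated correlation). Of 16 hemicellulose breakdown genes 12 fell and 1 rose, and 3 did not pass. AN1818 (endoxylanase GH10, log2 -3.49) and AN7401 (endoxylanase GH10, log2 -2.54) were among those called. The median was -0.98, -0.98 within slide 1 and -0.97 within slide 2 (adjusted p = 3.1e-05, 0.394 with estimated correlation). All 6 starch breakdown genes fell. AN8953 (alpha-glucosidase, log2 -4.11) and AN3402 (alpha-amylase, log2 -2.19) were among them. Their median was -1.57, -1.46 within slide 1 and -1.78 within slide 2 (adjusted p = 0.00196, 0.399 with estimated correlation). Of 21 sterigmatocystin cluster genes 19 fell and 1 rose, and 1 did not pass. AN7823 (log2 2.21) and AN7807 (log2 -2.08) were among those called. Their median was -1.66, -1.72 within slide 1 and -1.55 within slide 2 (adjusted p = 1.3e-09, 0.394 with estimated correlation).

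All 10 dba polyketide cluster genes fell. AN7898 (log2 -4.49) and AN7899 (log2 -4.33) were among them. The median was -4.08, -4.05 within slide 1 and -4.13 within slide 2 (adjusted p = 1.02e-08, 0.373 with estimated correlation). Of 6 hydrophobins 5 rose and none fell, and 1 did not pass. AN1837 (log2 4.13), rodA (AN8803, log2 3.66) and AN0940 (log2 3.35) were among those called. Their median was 2.56, 2.59 within slide 1 and 2.57 within slide 2 (adjusted p = 1.04e-05, 0.117 with estimated correlation). Of 14 asexual development genes 11 rose and none fell, and 3 did not pass. ivoB (AN0231, conidiophore pigment, log2 1.93) and brlA (AN0973, log2 1.77) were among those called. Their median was 0.29 (0.24 with dim members at their bound), 0.29 within slide 1 and 0.29 within slide 2 (adjusted p = 0.00031, 0.224 with estimated correlation). All 5 orsellinic acid cluster genes rose. AN7909 (polyketide synthase, log2 3.14) and AN7911 (log2 2.78) were among them. The median was 2.28, 2.22 within slide 1 and 2.39 within slide 2 (adjusted p = 0.00426, 0.394 with estimated correlation). All 6 austinol cluster genes rose. AN9249 (log2 2.61, TNO2A3 well above background on 1 of 3 arrays) and AN9253 (log2 2.15, TNO2A3 well above background on 1 of 3 arrays) were among them. Their median was 0.76 (0.68 with dim members at their bound), 0.87 within slide 1 and 0.54 within slide 2 (adjusted p = 1.58e-05, 0.117 with estimated correlation).

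Of 8 gluconeogenesis, glyoxylate and acetate genes 7 rose and none fell, and 1 did not pass. acuF (AN1918, phosphoenolpyruvate carboxykinase, log2 1.54) and AN6653 (malate synthase, log2 1.03) were among those called. Their median was 0.45, 0.49 within slide 1 and 0.44 within slide 2 (adjusted p = 0.00255, 0.373 with estimated correlation). Of 11 starvation and autolysis genes 7 rose and 2 fell, and 2 did not pass. chiA1 (AN8241, chitinase, log2 -3.09) and AN4871 (chitinase, log2 1.65) were among those called. The median was 0.26, 0.43 within slide 1 and 0.23 within slide 2 (adjusted p = 0.0385, 0.373 with estimated correlation). The starvation call was lost with the processed signals (camera adjusted p = 0.0925). In total 4385 of 8532 genes passed, 2273 higher and 2112 lower, and 393 of them by more than 2-fold (153 and 240). Above 2-fold there were 873 with the processed signals and 156 under the stricter filter. 6235 of all 8532 genes had all 3 arrays on one side (25% by chance). 4683 genes passed with slide as a block.

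Counts of higher and lower members in the other lists were 1 and 4 of 7 in carbon regulators (AN3369, cellulase regulator, log2 -1.15), 1 and 3 of 7 in sugar transport (AN2814, cellodextrin and lactose transporter, log2 -2.06) and 1 and 1 of 21 in MAP kinase signalling (tcsB, AN1800, histidine kinase, log2 -0.72). They were 5 and 4 of 14 in cell wall synthesis (ags1, AN3307, log2 -1.24), 2 and 1 of 7 in sexual development (AN7349, log2 1.42) and 0 and 1 of 3 in the penicillin cluster (AN2622, log2 -0.57). Further counts were 1 and 0 of 2 in the asperthecin cluster (AN6001, log2 0.28), 1 and 4 of 8 in oxidative stress (cat1, AN9339, log2 -0.62) and 4 and 1 of 7 in osmolytes and trehalose (AN5635, neutral trehalase, log2 0.40). Higher and lower members numbered 3 and 0 of 3 in the terrequinone cluster, 1 and 0 of 4 in the emericellamide cluster, 1 and 0 of 6 in heat shock proteins, 3 and 3 of 10 in glycolysis, 1 and 2 of 4 in ethanol metabolism, 1 and 5 of 11 in nitrogen metabolism, 4 and 0 of 7 in iron and siderophores, 0 and 1 of 3 in strain markers, 4 and 0 of 5 in the asperfuranone cluster and 2 and 0 of 3 in the monodictyphenone cluster. AN2621 and AN2623 of the penicillin cluster did not pass (-0.09 and 0.03). MAP kinase signalling 0 and 1, oxidative stress 1 and 5, osmolytes and trehalose 5 and 1, sterigmatocystin 2 and 19 and monodictyphenone 3 and 0 were higher and lower adjusted over the list alone, with other counts unchanged. Cell wall synthesis differed in sign between median, mean and test. With ratios scaled to one spread AN11584 read -5.03 and AN5046 4.02, and with the processed signals -6.35 and 5.50.

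**Figure D3:**
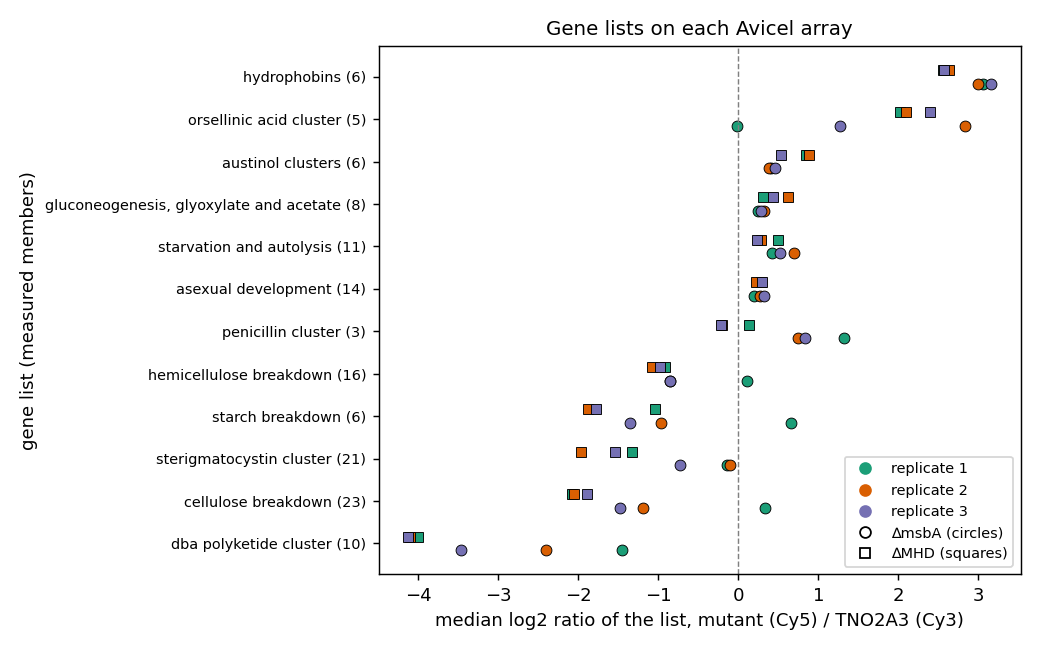
Median log2 ratio (mutant over TNO2A3) of 12 gene lists on each Avicel array, with circles for ∆msbA, squares for ∆MHD, colours for replicate numbers and the count of measured genes beside each list. The cellulose breakdown medians were 0.34, -1.19 and -1.48 in ∆msbA, and -2.08, -2.06 and -1.90 in ∆MHD.

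How far did the effect of ∆msbA differ between media? The effect was higher on Avicel than in YUU for ccpA (AN10109, adjusted p = 1.84e-12) and AN10573 (adjusted p = 8.05e-11), and lower for AN8619 (adjusted p = 8.88e-10) and AN3339 (adjusted p = 2.57e-11). Each was dim in both colours in YUU, so no difference is given. AN7041 fell in both media, with a difference of 0.16 (SE 0.10, adjusted p = 0.2), which passed without array 1 of ∆msbA on Avicel (0.15) and with ratios scaled to one spread (0.94). Of 6 heat shock proteins 5 were higher and none were lower, and 1 did not pass. AN0858 (log2 1.61) and AN2530 (small heat shock protein, log2 1.13) were among those called. Their median was 0.70, 0.49 within slide 2 and 0.57 with slide as a block (adjusted p = 0.00934, 0.447 with estimated correlation). Of 11 starvation and autolysis genes 9 were higher and 1 was lower, and 1 did not pass. mep20 (AN7962, dim in both colours in YUU, adjusted p = 1.1e-05) and AN4871 (log2 1.59) were among those called. The median was 0.72 (2 dim in both colours in YUU), 0.79 within slide 2 and 0.81 with slide as a block (adjusted p = 0.00135, 0.193 with estimated correlation).

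Of 14 asexual development genes 6 were higher and none were lower, and 8 did not pass. ivoA (AN10576, dim in both colours in YUU, adjusted p = 1.36e-10) and yA (AN6635, log2 1.87) were among those called. Their median was 0.21 (4 dim in both colours in YUU), 0.24 within slide 2 and 0.25 with slide as a block (adjusted p = 0.0138, 0.433 with estimated correlation). Of 8 gluconeogenesis, glyoxylate and acetate genes 4 were higher and none were lower, and 4 did not pass. AN5634 (log2 1.52) and fbp1 (AN5604, log2 0.93) were among those called. The median was 0.20, 0.28 within slide 2 and 0.22 with slide as a block (adjusted p = 0.0295, 0.447 with estimated correlation). Of 11 nitrogen metabolism genes 6 were lower and none were higher, and 5 did not pass. AN9470 (log2 -0.83) and AN2944 (nitrogen regulator, log2 -0.53) were among those called. Their median was -0.24, -0.21 within slide 2 and -0.29 with slide as a block (adjusted p = 0.0358, 0.433 with estimated correlation). No difference of effect is given for hydrophobins (3 of 6, 3.8e-05, 0.193), dba polyketide (9 of 10, 2.46e-05, 0.447) and austinol (5 of 6, 0.00503, 0.317), with the members dim in both colours in YUU, the camera adjusted p and the one with estimated correlation in brackets, since these p restate the Avicel shift. With slide as a block the heat shock (camera adjusted p = 0.0699) and gluconeogenesis (0.0864) calls were lost. In total 3671 of 8532 genes passed, 1791 higher and 1880 lower on Avicel, and 432 of them by more than 2-fold (215 and 217). Above 2-fold the count was 1070 with the processed signals and 208 under the stricter filter. 4493 of all 8532 genes had groups that did not overlap (10% by chance). The share higher was 48.8%, against 53.3% with the processed signals. 3282 genes passed with slide as a block.

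Lists without a called shift had higher and lower members as 2 and 8 of 23 in cellulose breakdown, 1 and 7 of 16 in hemicellulose breakdown, 0 and 1 of 6 in starch breakdown, 1 and 4 of 7 in carbon regulators, 1 and 3 of 7 in sugar transport, 3 and 1 of 21 in MAP kinase signalling, 4 and 6 of 14 in cell wall synthesis, 3 and 1 of 7 in sexual development, 0 and 3 of 3 in the penicillin cluster, 1 and 0 of 5 in the orsellinic acid cluster, 1 and 0 of 2 in the asperthecin cluster, 0 and 3 of 4 in the emericellamide cluster, 2 and 3 of 8 in oxidative stress, 3 and 0 of 7 in osmolytes and trehalose, 0 and 5 of 10 in glycolysis, 0 and 2 of 4 in ethanol metabolism, 2 and 2 of 7 in iron and siderophores, 0 and 2 of 3 in strain markers, 3 and 7 of 21 in the sterigmatocystin cluster and 0 and 1 of 3 in the monodictyphenone cluster. No member passed in terrequinone and asperfuranone. Members dim in YUU were those given for YUU above. Cellulose breakdown 2 and 9, hemicellulose breakdown 1 and 8, starch breakdown 0 and 0, MAP kinase signalling 3 and 0, cell wall synthesis 4 and 7, sexual development 4 and 2, oxidative stress 3 and 3 and sterigmatocystin 3 and 9 were higher and lower adjusted over the list alone, with other counts unchanged. MAP kinase signalling and iron and siderophores differed in sign between median, mean and test. Without array 1 of ∆msbA on Avicel 14 lists passed against 8, with 3793 genes called. Added were cellulose breakdown (median -1.39, camera adjusted p = 6.09e-07, 10 of 23 dim in YUU) and hemicellulose breakdown (-0.97, 1.99e-05, 6 of 16). Penicillin (-0.71, 0.0404), orsellinic acid (1.88, 0.0132, 2 of 5 dim) and glycolysis (-0.37, 0.0404) were added too. Starch breakdown also passed (0.000927), but no difference is given, since 4 of 6 members were dim in YUU. Of the called genes 525 (14.3%) were dim in both colours in YUU, where no effect was measured. Without replicate 2 the count was 2352.

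The effect of ∆MHD was compared between media in the same way. It was lower on Avicel for AN11584 (adjusted p = 3.3e-06) and AN7903 (adjusted p = 1.5e-06), and higher for AN5046 (adjusted p = 3.24e-11) and ivoA (AN10576, adjusted p = 7.24e-11). Each was dim in both colours in YUU, so no difference is given. AN7041, lower in YUU, was relatively higher on Avicel (difference log2 0.74, SE 0.10, 1.66-fold, adjusted p = 0.000114), at 0.81 within slide 2 and 0.79 with slide as a block. Of 23 cellulose breakdown genes 17 were lower and none were higher, and 6 did not pass. cbhC (AN5282, dim in both colours in YUU, adjusted p = 0.000491) and AN6428 (lytic polysaccharide monooxygenase AA9, dim in both colours in YUU, adjusted p = 4.16e-05) were among those called. Their median was -2.01 (11 dim in both colours in YUU), -1.79 within slide 2 and -2.11 with slide as a block (adjusted p = 5.6e-07, 0.418 with estimated correlation). Of 16 hemicellulose breakdown genes 12 were lower and 1 was higher, and 3 did not pass. The median was -1.09 (7 dim in both colours in YUU), -0.93 within slide 2 and -1.11 with slide as a block (adjusted p = 5.51e-05, 0.418 with estimated correlation). All 3 penicillin cluster genes were lower, namely AN2622 (log2 -1.95), AN2621 (log2 -0.98) and AN2623 (log2 -0.91). Their median was -0.98, -1.04 within slide 2 and -0.98 with slide as a block (adjusted p = 0.00717, 0.345 with estimated correlation).

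Of 14 asexual development genes 6 were higher and none were lower, and 8 did not pass. ivoB (AN0231, log2 1.83) and brlA (AN0973, dim in both colours in YUU, adjusted p = 5.76e-08) were among those called. The median was 0.22 (3 dim in both colours in YUU), 0.19 within slide 2 and 0.20 with slide as a block (adjusted p = 0.000942, 0.314 with estimated correlation). All 5 orsellinic acid cluster genes were higher. Their median was 2.13 (2 dim in both colours in YUU), 2.17 within slide 2 and 1.89 with slide as a block (adjusted p = 0.0047, 0.418 with estimated correlation).

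Of 8 gluconeogenesis, glyoxylate and acetate genes 5 were higher and none were lower, and 3 did not pass. acuF (AN1918, log2 1.77) and fbp1 (AN5604, log2 0.97) were among those called. The median was 0.40, 0.37 within slide 2 and 0.35 with slide as a block (adjusted p = 0.000911, 0.334 with estimated correlation). No difference of effect is given either for starch breakdown (4 of 6, 0.00367, 0.445), hydrophobins (4 of 6, 5.6e-07, 0.0735), sterigmatocystin (17 of 21, 1.16e-09, 0.345), dba polyketide (9 of 10, 2.86e-09, 0.34) and austinol (5 of 6, 2.82e-06, 0.0735), with the same values in brackets. In total 3215 of 8532 genes passed, 1539 higher and 1676 lower on Avicel, and 390 of them by more than 2-fold (154 and 236). Above 2-fold the count was 913 with the processed signals and 157 under the stricter filter. 4368 of all 8532 genes had groups that did not overlap (10% by chance). The share higher was 47.9%, against 55% with the processed signals. 2847 genes passed with slide as a block.

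The other lists had higher and lower members as 1 and 4 of 7 in carbon regulators, 1 and 3 of 7 in sugar transport, 0 and 2 of 21 in MAP kinase signalling, 4 and 4 of 14 in cell wall synthesis, 5 and 2 of 11 in starvation and autolysis, 2 and 0 of 7 in sexual development, 1 and 0 of 2 in the asperthecin cluster, 2 and 0 of 3 in the terrequinone cluster, 0 and 2 of 8 in oxidative stress, 4 and 0 of 7 in osmolytes and trehalose, 1 and 4 of 10 in glycolysis, 0 and 2 of 4 in ethanol metabolism, 0 and 4 of 11 in nitrogen metabolism, 3 and 2 of 7 in iron and siderophores, 3 and 0 of 5 in the asperfuranone cluster and 2 and 0 of 3 in the monodictyphenone cluster. No member passed in emericellamide, heat shock proteins and strain markers. Members dim in YUU were those given for YUU above. Cellulose breakdown 0 and 18, sugar transport 1 and 4, MAP kinase signalling 0 and 1, starvation and autolysis 6 and 3, asexual development 8 and 0, terrequinone 3 and 0, glycolysis 1 and 5, gluconeogenesis, glyoxylate and acetate 6 and 0, iron and siderophores 4 and 2 and asperfuranone 4 and 0 were higher and lower adjusted over the list alone, with other counts unchanged. Cell wall synthesis, sexual development and heat shock proteins differed in sign between median, mean and test. Of the called genes 602 (18.7%) were dim in both colours in YUU, where no effect was measured. The count was 2127 under the stricter filter and 2055 without replicate 2.

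**Figure D4:**
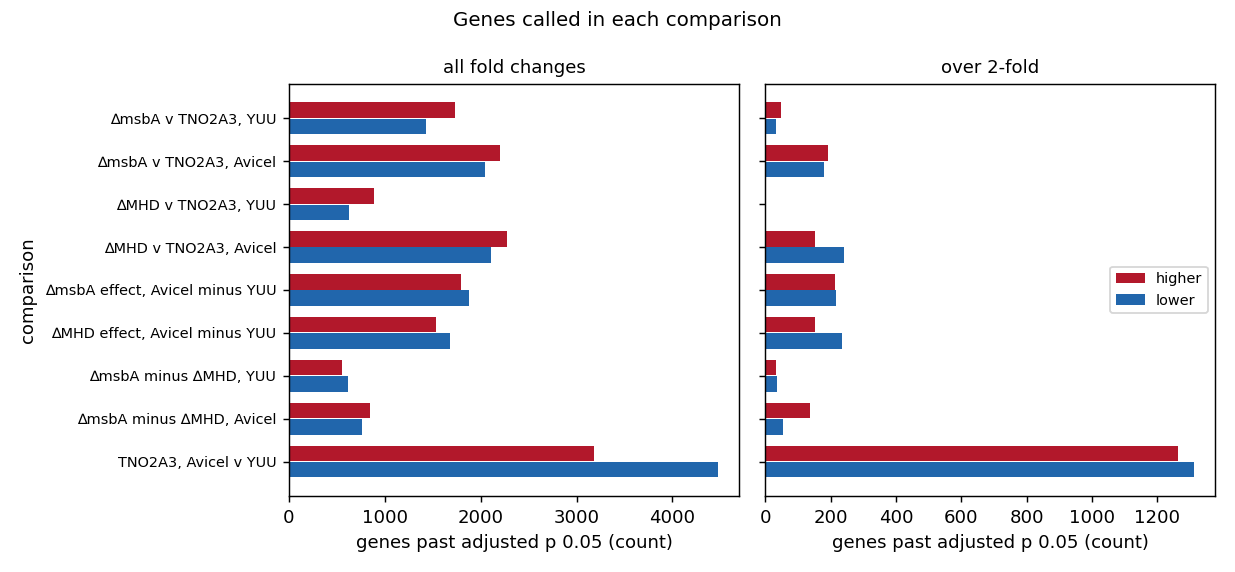
Number of genes called higher (red) and lower (blue) in each comparison, for all fold changes (left panel) and above 2-fold (right panel). The counts ran from 1167 between the mutants in YUU to 7655 for TNO2A3 between media.

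Where did the mutants differ from each other in complete medium? Relative to ∆MHD, ∆msbA had less of AN2571 (log2 -2.72, SE 0.28, 6.58-fold, adjusted p = 5.78e-05) and AN7041 (log2 -1.96, SE 0.10, 3.89-fold, adjusted p = 4.07e-07), and more of AN8333 (log2 2.32, SE 0.20, 5-fold, adjusted p = 1.47e-05) and AN9108 (log2 1.72, SE 0.11, 3.29-fold, adjusted p = 1.97e-06). Of 6 heat shock proteins 3 were lower and none were higher, and 3 did not pass. AN0858 (log2 -1.30) and hsp70 (AN5129, log2 -0.60) were among those called. Their median was -0.56, -0.52 within slide 2 and -0.53 within slide 3 (adjusted p = 0.00188, 0.986 with estimated correlation). AN7041 read -1.93 within slide 2 and -1.97 within slide 3. In total 1167 of 8532 genes passed, 554 higher and 613 lower in ∆msbA, and 68 of them by more than 2-fold (32 and 36). Above 2-fold the count was 221 with the processed signals. 2964 of all 8532 genes had groups that did not overlap (10% by chance). 1500 genes passed with slide as a block.

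In the other lists higher and lower members numbered 1 and 0 of 23 in cellulose breakdown, 1 and 1 of 21 in MAP kinase signalling, 3 and 1 of 14 in cell wall synthesis, 0 and 1 of 11 in starvation and autolysis, 1 and 0 of 3 in the penicillin cluster, 1 and 0 of 4 in the emericellamide cluster, 1 and 1 of 8 in oxidative stress, 0 and 1 of 10 in glycolysis, 1 and 1 of 8 in gluconeogenesis, glyoxylate and acetate, 1 and 0 of 11 in nitrogen metabolism and 1 and 0 of 7 in iron and siderophores. No member passed in hemicellulose breakdown, starch breakdown, carbon regulators, sugar transport, hydrophobins, asexual development, sexual development, orsellinic acid, asperthecin, terrequinone, osmolytes and trehalose, ethanol metabolism, strain markers, sterigmatocystin, dba polyketide, austinol, asperfuranone and monodictyphenone. Lists with at least as many members dim as not were those of ∆msbA in YUU, with the same counts. Cell wall synthesis 5 and 2, starvation and autolysis 0 and 3, oxidative stress 1 and 3, osmolytes and trehalose 0 and 4, heat shock proteins 0 and 4, glycolysis 0 and 2 and iron and siderophores 1 and 2 were higher and lower adjusted over the list alone, with other counts unchanged. Cellulose breakdown, carbon regulators, MAP kinase signalling, starvation and autolysis, asexual development, orsellinic acid, ethanol metabolism, iron and siderophores and monodictyphenone differed in sign between median, mean and test. With a random block of medium and number the count was 1897, and without replicate 1, 2 or 3 it was 670, 369 and 663. AN8333 read 2.46 with the processed signals.

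The mutants were then compared on Avicel. Relative to ∆MHD, ∆msbA had less of AN8619 (log2 -3.57, SE 0.17, 11.8-fold, adjusted p = 7.86e-08) and AN3339 (log2 -3.42, SE 0.11, 10.7-fold, adjusted p = 1.5e-08), and more of AN7396 (beta-glucosidase GH3, log2 3.93, SE 0.52, 15.2-fold, adjusted p = 0.000261, without array 1 of ∆msbA on Avicel 3.27) and AN9390 (log2 2.77, SE 0.40, 6.82-fold, adjusted p = 5e-04). AN7041 was lower in ∆msbA (log2 -2.53, SE 0.10, 5.78-fold, adjusted p = 2.15e-08), at -2.53 within slide 1 and -2.54 within slide 2. Of 21 sterigmatocystin cluster genes 19 were higher and none were lower, and 2 did not pass. AN7821 (log2 1.92) and AN7817 (log2 1.70) were among those called. The median was 1.19, 1.40 within slide 1 and 0.75 within slide 2 (adjusted p = 1.13e-14, 0.401 with estimated correlation). All 3 penicillin cluster genes were higher. AN2622 (log2 1.59) and AN2623 (log2 0.95) were among them. Their median was 0.95, 0.95 within slide 1 and 0.94 within slide 2 (adjusted p = 0.00132, 0.401 with estimated correlation). Of 23 cellulose breakdown genes 15 were higher and none were lower, and 8 did not pass. AN6428 (log2 2.35, without replicate 1 1.72, without array 1 of ∆msbA on Avicel 1.68) was among those called. Their median was 1.05, 1.41 within slide 1 and 0.30 within slide 2 (adjusted p = 6.66e-07, 0.569 with estimated correlation). Of 16 hemicellulose breakdown genes 7 were higher and 1 was lower, and 8 did not pass. AN5267 (feruloyl esterase, log2 1.41) was among those called. The median was 0.54, 0.64 within slide 1 and 0.14 within slide 2 (adjusted p = 0.00126, 0.574 with estimated correlation).

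Of 6 starch breakdown genes 2 were higher and none were lower, and 4 did not pass. AN8953 (log2 3.12, without replicate 1 2.30, without array 1 of ∆msbA on Avicel 2.16) was among those called. Their median was 0.95, 1.25 within slide 1 and 0.35 within slide 2 (adjusted p = 0.0164, 0.574 with estimated correlation). Of 10 dba polyketide cluster genes 8 were higher and none were lower, and 2 did not pass. AN7894 (log2 1.81, without replicate 2 1.74, not called, with only the groups compared 1.81, not called) was among those called. Their median was 1.49, 2.05 within slide 1 and 0.36 within slide 2 (adjusted p = 3.85e-05, 0.569 with estimated correlation). Of 6 austinol cluster genes 5 were lower and none were higher, and 1 did not pass. AN9249 (log2 -0.85, with the processed signals -0.69, not called) was among those called. The median was -0.40, -0.52 within slide 1 and -0.21 within slide 2 (adjusted p = 4.99e-05, 0.265 with estimated correlation). Of 5 asperfuranone cluster genes 4 were lower and none were higher, and 1 did not pass. AN1036 (at least 2.08-fold lower, adjusted p = 0.000754) was among those called. Their median was -1.09 (-1.06 with dim members at their bound), -1.11 within slide 1 and -1.03 within slide 2 (adjusted p = 0.000818, 0.556 with estimated correlation). All 3 monodictyphenone cluster genes were lower. AN0148 (log2 -0.54) was among them. Their median was -0.53, -0.48 within slide 1 and -0.54 within slide 2 (adjusted p = 0.00663, 0.401 with estimated correlation).

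Of 4 emericellamide cluster genes 2 were lower and none were higher, and 2 did not pass. AN2545 (log2 -0.74, with the processed signals -0.91, not called, without replicate 2 -0.78, not called) was among those called. The median was -0.37, -0.36 within slide 1 and -0.41 within slide 2 (adjusted p = 0.0443, 0.574 with estimated correlation). Of 10 glycolysis genes 4 were lower and none were higher, and 6 did not pass. pgkA (AN1246, phosphoglycerate kinase, log2 -0.49, without replicate 2 -0.41, not called, without replicate 3 -0.42, not called) was among those called. Their median was -0.22, -0.19 within slide 1 and -0.28 within slide 2 (adjusted p = 0.00847, 0.401 with estimated correlation). The emericellamide call was lost with the processed signals (camera adjusted p = 0.249), and hemicellulose, starch and emericellamide under fry (adjusted p = 0.0621, 0.0839 and 0.0621). In total 1615 of 8532 genes passed, 849 higher and 766 lower in ∆msbA, and 192 of them by more than 2-fold (136 and 56). Above 2-fold the count was 407 with the processed signals and 64 under the stricter filter. 2847 of all 8532 genes had groups that did not overlap (10% by chance). The share higher was 52.6%, against 49.9% with the processed signals and 48% under the stricter filter. 1888 genes passed with slide as a block.

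Counts of higher and lower members in the other lists were 1 and 0 of 7 in carbon regulators, 2 and 0 of 7 in sugar transport, 3 and 0 of 21 in MAP kinase signalling, 2 and 0 of 14 in cell wall synthesis, 5 and 1 of 11 in starvation and autolysis, 1 and 2 of 6 in hydrophobins, 2 and 2 of 14 in asexual development, 1 and 0 of 7 in sexual development, 1 and 2 of 8 in oxidative stress, 0 and 2 of 7 in osmolytes and trehalose, 2 and 0 of 6 in heat shock proteins, 0 and 3 of 8 in gluconeogenesis, glyoxylate and acetate, 1 and 2 of 4 in ethanol metabolism, 0 and 1 of 11 in nitrogen metabolism and 0 and 1 of 7 in iron and siderophores. No member passed in orsellinic acid, asperthecin, terrequinone and strain markers. Hemicellulose breakdown 9 and 1, starch breakdown 3 and 0, carbon regulators 0 and 0, sugar transport 3 and 0, hydrophobins 1 and 3, asexual development 2 and 3, sexual development 3 and 0, emericellamide 0 and 3, glycolysis 0 and 5, gluconeogenesis, glyoxylate and acetate 0 and 4, ethanol metabolism 1 and 3, nitrogen metabolism 0 and 0, dba polyketide 10 and 0, austinol 0 and 6 and asperfuranone 0 and 5 were higher and lower adjusted over the list alone, with other counts unchanged. Nitrogen metabolism differed in sign between median, mean and test. Without array 1 of ∆msbA on Avicel the median difference was 0.53 for cellulose breakdown, 0.28 for hemicellulose breakdown, 0.29 for starch breakdown, 1.01 for the dba cluster, 1.12 for sterigmatocystin and -0.31 for monodictyphenone, where 2 genes were lower, with 1516 genes called, and the emericellamide call was lost (camera adjusted p = 0.187, median -0.23). The count was 950 under the stricter filter, 989 with only the groups compared, and 761 without replicate 2. AN8619 read -2.79 with ratios scaled to one spread.

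How did TNO2A3 respond to the move to Avicel? Relative to YUU, genes higher on Avicel included cbhC (AN5282, at least 531-fold higher, adjusted p = 8.32e-09), AN7894 (at least 496-fold higher, adjusted p = 4.39e-11) and AN5176 (at least 557-fold higher, adjusted p = 5.78e-10). Among the largest losses were AN2319 (log2 -5.32, SE 0.17, 39.9-fold, adjusted p = 3.81e-08) and AN5860 (hexose transporter, log2 -4.78, SE 0.27, 27.5-fold, adjusted p = 1.01e-06). AN7041 fell (log2 -0.56, SE 0.09, 1.47-fold, adjusted p = 0.000547), at -0.60 within slide 2. Of 23 cellulose breakdown genes 20 rose and 2 fell, and 1 did not pass. AN7230 (cellobiose dehydrogenase, at least 450-fold higher, adjusted p = 4.57e-09) was among those called. Their median was 4.23, 4.47 within slide 2 (adjusted p = 4.45e-06, 0.489 with estimated correlation). Of 16 hemicellulose breakdown genes 12 rose and 3 fell, and 1 did not pass. AN5267 (at least 142-fold higher, adjusted p = 1.3e-10) and AN6093 (acetyl xylan esterase, log2 6.57) were among those called. The median was 1.93 (1.74 with dim members at their bound), 1.92 within slide 2 (adjusted p = 0.00288, 0.489 with estimated correlation). All 6 starch breakdown genes rose. AN8953 (at least 98.3-fold higher, adjusted p = 4.45e-07) and AN3402 (at least 22.9-fold higher, adjusted p = 5.96e-07) were among them. Their median was 2.76 (2.58 with dim members at their bound), 2.93 within slide 2 (adjusted p = 0.0149, 0.489 with estimated correlation). Of 7 sugar transport genes 6 rose and 1 fell. AN2814 (at least 240-fold higher, adjusted p = 4.96e-10) and AN8347 (cellodextrin transporter, at least 176-fold higher, adjusted p = 2.11e-10) were among them. Their median was 5.74 (5.67 with dim members at their bound), 5.91 within slide 2 (adjusted p = 0.0058, 0.279 with estimated correlation).

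Of 7 carbon regulators 6 rose and 1 fell. AN3369 (log2 3.13) and AN5808 (cellulase regulator, at least 4.11-fold higher, adjusted p = 6.39e-09) were among them. Their median was 0.97, 0.89 within slide 2 (adjusted p = 0.0238, 0.384 with estimated correlation). All 11 starvation and autolysis genes rose. mep20 (AN7962, at least 121-fold higher, adjusted p = 9.8e-09) and AN1502 (N-acetylglucosaminidase, log2 5.85) were among them. The median was 2.79, 2.76 within slide 2 (adjusted p = 0.00013, 0.186 with estimated correlation). All 4 emericellamide cluster genes rose. AN2549 (log2 4.10) and AN2545 (at least 5.09-fold higher, adjusted p = 1.52e-08) were among them. Their median was 2.07 (2.01 with dim members at their bound), 2.02 within slide 2 (adjusted p = 0.0149, 0.489 with estimated correlation). All 6 heat shock proteins fell. AN0858 (log2 -2.71) and hsp60 (AN6089, log2 -2.46) were among them. The median was -1.98, -1.97 within slide 2 (adjusted p = 0.0398, 0.489 with estimated correlation).

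All 10 glycolysis genes fell. AN3223 (phosphofructokinase, log2 -3.86) and pgkA (AN1246, log2 -3.21) were among them. The median was -1.59, -1.53 within slide 2 (adjusted p = 0.00949, 0.485 with estimated correlation). All 21 sterigmatocystin cluster genes rose. AN7809 (at least 154-fold higher, adjusted p = 6.03e-10) and AN7825 (log2 7.43) were among them. Their median was 5.38 (5.05 with dim members at their bound), 5.44 within slide 2 (adjusted p = 3.77e-09, 0.485 with estimated correlation). All 10 dba polyketide cluster genes rose. AN7894 (above) and AN7893 (at least 348-fold higher, adjusted p = 4.39e-11) were among them. The median was 6.73 (6.59 with dim members at their bound), 6.57 within slide 2 (adjusted p = 4.45e-06, 0.186 with estimated correlation). In total 7655 of 8532 genes passed, 3180 higher and 4475 lower, and 2575 of them by more than 2-fold (1263 and 1312). Above 2-fold the count was 4376 with the processed signals. 7736 of all 8532 genes had groups that did not overlap (10% by chance). 7107 genes passed with slide as a block.

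Counts of higher and lower members in the other lists were 7 and 5 of 21 in MAP kinase signalling, 5 and 8 of 14 in cell wall synthesis, 5 and 1 of 6 in hydrophobins, 7 and 5 of 14 in asexual development, 4 and 1 of 7 in sexual development, 2 and 0 of 3 in the penicillin cluster, 5 and 0 of 5 in the orsellinic acid cluster, 2 and 0 of 2 in the asperthecin cluster, 3 and 0 of 3 in the terrequinone cluster, 2 and 5 of 8 in oxidative stress, 1 and 6 of 7 in osmolytes and trehalose, 3 and 4 of 8 in gluconeogenesis, glyoxylate and acetate, 3 and 1 of 4 in ethanol metabolism, 2 and 9 of 11 in nitrogen metabolism, 2 and 4 of 7 in iron and siderophores, 0 and 2 of 3 in strain markers, 2 and 0 of 6 in the austinol clusters, 1 and 0 of 5 in the asperfuranone cluster and 3 and 0 of 3 in the monodictyphenone cluster. Members dim in both media, without a fold, were 3 of 6 in austinol, 2 of 11 in nitrogen metabolism and 1 of 14 in asexual development. Asperfuranone 0 and 0 were higher and lower adjusted over the list alone, with other counts unchanged. Oxidative stress and gluconeogenesis, glyoxylate and acetate differed in sign between median, mean and test. Of the genes above 2-fold 604 were dim in one medium. The share higher was 41.5%, against 32.8% with median scaling of Cy3 (151 genes called the opposite way) and 47.7% with the processed signals (213 genes). AN2319 read -5.76 and -6.80 with these.

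Finally, the genes moved by each mutant were compared within a medium. On Avicel the hydrophobins AN1837 and rodA and the pigment gene ivoA rose in both mutants, and all 10 measured dba genes fell in both. Across 8532 genes the mean ratios of ∆msbA and ∆MHD had r = 0.49 in YUU (covariance 0.0175) and r = 0.76 on Avicel (covariance 0.1787). Simulated unchanged mutants sharing TNO2A3 samples gave covariances of 0.0014 and 0.0045, and r = 0.50 by construction. Arrays of unlike numbers had mean r = 0.39 in YUU and 0.68 on Avicel. In YUU 554 genes were higher in both mutants (180 by chance), 359 lower in both (105) and 86 opposite (276). On Avicel the counts were 1471 (585), 1394 (506) and 193 (1088). Part of this excess may come from the shared TNO2A3 samples, since 3 controls per medium cannot be split. A dye effect of probes may add to it in either medium, since both mutants carried Cy5. Between media the ratios of ∆msbA had r = 0.11 and those of ∆MHD r = 0.09. Of 1667 genes called in both media in ∆msbA 1124 moved one way and 543 opposite ways, and of 786 in ∆MHD 608 and 178.

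**Figure D5:**
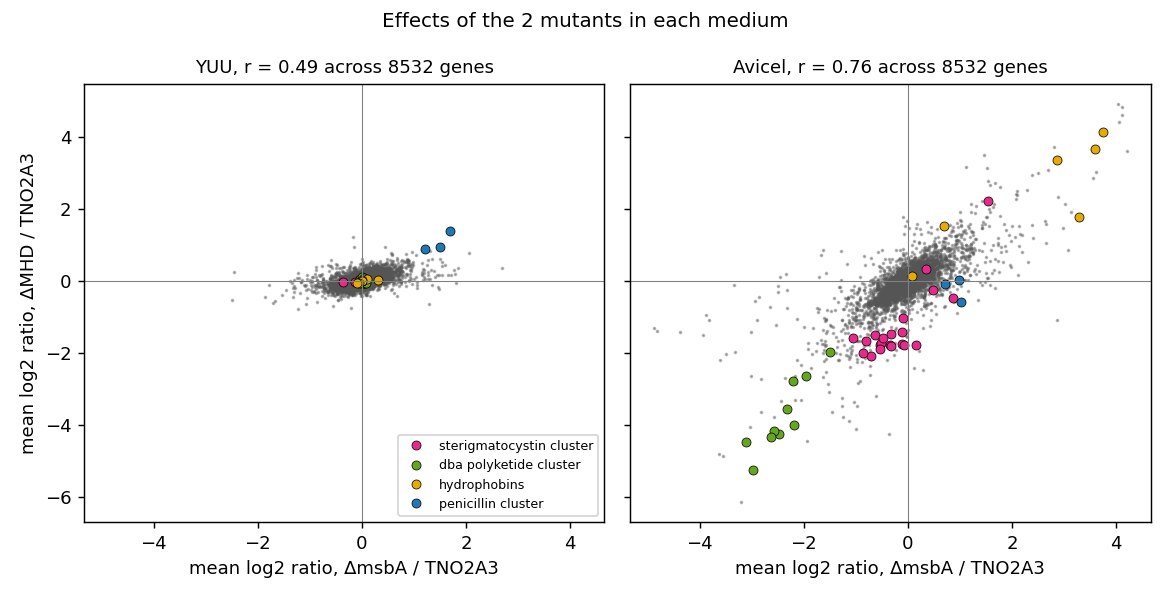
Mean log2 ratio of ∆MHD against that of ∆msbA, each over TNO2A3, for 8532 genes in YUU and on Avicel, with sterigmatocystin, dba, hydrophobin and penicillin genes coloured. Pearson r was 0.49 in YUU and 0.76 on Avicel.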

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

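Of the tests below, the dye test for ∆MHD in YUU, the test of the TNO2A3 sample on array 1 and the other splits were chosen before the result was seen, and the rest only after it. A test of the difference itself set apart 3671 genes whose ∆msbA effect, and 3215 whose ∆MHD effect, was not the same on Avicel as in YUU. It likewise set apart 1167 genes between the mutants in YUU and 1615 on Avicel. Called genes moved opposite ways in both media for 543 genes in ∆msbA and 178 in ∆MHD, and 193 genes moved opposite ways in the mutants on Avicel. AN7041 in ∆MHD was 0.74 higher in log2 on Avicel than in YUU. Groups of 3 were not tested for a single deviating array.

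Array 1 of ∆msbA on Avicel lay apart from arrays 2 and 3, with a cellulose breakdown median of 0.34 against -1.19 and -1.48. A mislabelled array was excluded by AN7041 at -2.33 on it. Slide was excluded, since the correlation of arrays 1 and 2 of one slide minus that of arrays 2 and 3 of different slides was -0.13, and TNO2A3 RNA in the Cy5 sample by a hydrophobin median at 99.4% of the other arrays. The TNO2A3 sample was excluded, since the Cy3 deviation of cellulose and dba genes was 21.1% of what it would need. A culture that grew otherwise may explain the array, but no biological explanation was tested.

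Both mutants moved most called genes one way on Avicel. A shared TNO2A3 sample as the whole cause was excluded, since arrays of unlike numbers had a covariance at 94.6% of that of like numbers. A dye effect was excluded by a YUU shift at 8.57% of the Avicel shift, and slide by a covariance of arrays on different slides at 105% of that on one slide. A response to Avicel that both deletions alter may be the cause, which these arrays cannot separate from a difference in growth. Whether both deletions affect the same gene is not given.

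Many small changes were called in ∆MHD in YUU. A dye effect of probes might make them, and could not be told apart from the mutant, since 58.5% of these genes lay on the same side in both Avicel groups, against 39.4% if the side in YUU were independent. A mutant effect present in both media would raise that share too. Normalization as the whole cause was excluded by the 67.5% called the same way with the processed signals, and array 1, with the dimmest Cy5 signal, by a count without it at 1.31 times the lowest of the others.

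Exchanging Cy5 and Cy3 of 1 array in each comparison against TNO2A3 left the real arrangement as 1 of 4 to call as many genes. The highest other count was 0, and 23 for ∆msbA on Avicel. In the other 5 comparisons the real split was 1 of 10, with a highest other count of 0, and 2 between the mutants on Avicel. These splits are too few for a share under 0.05.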

How the results depend on the processing

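Only the fit without array 1 of ∆msbA on Avicel and the replicate block within each medium were chosen after the result was seen. The text names 179 genes in a comparison, 172 of which kept side and direction under each alternative (2129 of 2145 values, 14 weaker and 2 stronger). For the 831 that the rule gave it was 560, and 9239 of 10034 values, with 759 weaker, 27 stronger and 9 reversed. Counts of called genes moved beyond 1.5 times with only the groups compared (∆msbA on Avicel 2473 from 4240, the mutants on Avicel 989 from 1615), and under the stricter filter, which tests fewer genes (∆MHD between media 2127 from 3215, the mutants on Avicel 950). Scaling to one spread gave 2779 from 1515 for ∆MHD in YUU, and a random block 1897 from 1167 between the mutants in YUU. Leaving out a replicate, which leaves fewer arrays, gave 1926 to 2346 from 3158 (∆msbA in YUU), 2877 to 3913 from 4240 (∆msbA on Avicel), 516 to 678 from 1515 and 3076 to 3677 from 4385 (∆MHD in YUU and on Avicel), 2352 to 3793 from 3671 and 2055 to 2490 from 3215 (∆msbA and ∆MHD between media), and 369 to 670 from 1167 and 761 to 1516 from 1615 (the mutants in YUU and on Avicel). Called lists numbered 65 in the report, 0 with an estimated correlation, 127 under fry and 64 with the processed signals, and slide as a block left 5 of 8 for ∆msbA on Avicel and gave 6 from 8 and 13 from 11 between media (∆msbA and ∆MHD), and 12 from 11 between the mutants on Avicel. Oxidative stress in TNO2A3 turned direction under fry (adjusted p = 0.0474, 0.594 by camera). For the other moves the cause was not tested. Deviations of the same replicate number were correlated on Avicel (0.50, 0.37 and 0.35), which pairs the numbers there. They were less evenly so in YUU (0.09, 0.27 and 0.42, for Cy3 alone 0.26, 0.27 and 0.55). Across media log ratios were not (-0.11 to 0.10), but Cy3 alone gave 0.09 to 0.30. A replicate block over all arrays gave 3198, 4285, 1520, 4391, 3697, 3289, 1199, 1657 and 7671 called genes in the order of the methods text, and within each medium 1667 and 2210 between the mutants in YUU and on Avicel. Called lists were 12 from 11 with the first block for ∆MHD on Avicel and between media, and 3 from 1 and 12 from 11 with the other between the mutants in YUU and on Avicel. The correlation of both mutants was 0.40 to 0.53 in YUU and 0.72 to 0.80 on Avicel when a replicate was left out. Signal over background limits dim genes: 159 of 432 ∆msbA and 183 of 390 ∆MHD differences above 2-fold between media concern genes dim in YUU. Not run were the deposited table, the brightest probe (1 probe per gene) and lists by keyword (no descriptions).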

Other observations

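The runs of neighbours and the opposite genes were picked only after their values were seen, and the tests of a weaker response were written before. In locus order, runs of at least 4 genes moved more than 2-fold one way with at most 1 gene skipped. On Avicel ∆msbA lowered AN7873 to AN7884 (8 genes, median log2 -2.08), the dba run AN7893 to AN7906 (12 genes, -2.41) and AN0531 to AN0526 (5 genes, -1.84), and raised AN2606 to AN2611 (6 genes, 1.82). ∆MHD had 7 such runs with 52 genes, among them AN7804 to AN7818 in the sterigmatocystin cluster (17 genes, -1.78), AN7893 to AN7906 (12 genes, -4.08), AN3612 to AN3609 (4 genes, -2.86) and, raised, AN7909 to AN7914 (4 genes, 2.53). In 200 shuffled orders at most 1 run arose. Single genes went opposite ways in a mutant between media, such as AN7876 (-2.46 on Avicel and 1.07 in YUU) and AN2951 (-0.96 and 1.85) in ∆msbA, and AN2622 (-0.57 and 1.38) and frdA (AN10296, -1.44 and 0.72) in ∆MHD. On Avicel AN7396 was at 2.86 in ∆msbA and -1.07 in ∆MHD, and AN4532 at -1.62 and 0.85.

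A weaker response to Avicel in the mutants was tested as a hypothesis. Of 1263 genes more than 2-fold higher on Avicel in TNO2A3, ∆MHD had 557 lower (44.1%) and 365 higher (28.9%), and ∆msbA 502 (39.7%) and 396 (31.4%). Across genes, the TNO2A3 response and the mutant ratio from arrays of other numbers correlated, for ratios of numbers 1, 2 and 3, at -0.126, -0.187 and -0.163 for ∆MHD, and at 0.0355, -0.0868 and -0.163 for ∆msbA, where number 1 had the other sign. Genes lower on Avicel in TNO2A3 were also more often lower than higher in the mutants, with 449 (34.2%) against 230 (17.5%) in ∆MHD. These values may reflect a weaker response in part of the genes only, and cannot tell it from a change of other genes.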
